A study of Mus musculus with 32 samples.

How the data were processed

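Only the deposited processed values were used. The RNAi levels are log2 values made by RMA per the labels, whose software, version and probe annotation are not given there. The 2-colour values are, per the labels, log ratios of treated over untreated cells and were analysed as log2, since the base is not given in the sources used here; each array has a median of 0. Labels do not say how the ratios were background-corrected or normalized within an array. Groups, days and doses come from the labels. Each of the 14 RNAi arrays was analysed as an independent sample, so p values on them measure the spread between arrays. No sample was left out.

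Of 45101 probe sets, 64 control probe sets were set aside and 45037 tested, and 34945 of these carried exactly 1 gene name (932 several, 9160 none), which gave 18194 genes. Of 21106 probes on the 2-colour arrays 16657 had a value in every group and were tested, 10763 of them with values on all 18 arrays, and 13392 had exactly 1 gene name, which gave 12038 genes, 10995 of them on both platforms. Gene names came from the gene tables provided with the array platforms. No genome build is given, so no coordinates were used.

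Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 14 RNAi arrays or all 18 ratio arrays in one fit, no block, and Benjamini-Hochberg adjusted p under 0.05 as the call. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The design, the gene lists, the naming of genes and the alternatives were fixed before the data were examined. The day-by-day tests, the tests of whether treatments differ in their change over time, the fits without a DMSO day and the dye term for gene lists were added later.

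Genes named in the text are Pou5f1 and Nanog, plus those chosen by a rule among called genes with exactly 1 name that is not a clone or predicted name. For RNAi comparisons and treatment means these are the 10 largest rises and falls whose arrays do not overlap between groups (RNAi) or share the sign on all 6 arrays (treatments), and for the other comparisons the 5 largest each way, each gene by its most changed probe. Members of a list are examples in the order of their p, measured by the probe of highest mean on the RNAi arrays and by the most complete probe on the others. A gene can therefore carry different values, as Krt8 does after Pou5f1 RNAi (6.36 by the rule, 6.10 in its list). Genes outside the rule are said to be chosen after their values were seen. Probe sets of a gene were called in both directions in 0 of 361 pairs of a named gene and a comparison.

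The 18 lists are pluripotency, trophectoderm, primitive endoderm, primitive streak and mesoderm, epiblast, neural, retinoid response, Nodal and BMP signalling, fibroblast and smooth muscle, p53 response, interferon response, cell cycle, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, imprinted genes, germ cell and 2-cell stage, and polycomb and chromatin. They share some genes, and were tested with at least 5 measured members. The plan named limma's camera, which cannot take missing values, so its version for a ranked statistic (cameraPR on the moderated z) was run on both platforms, with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The p with a correlation estimated from the residuals is given where it loses the call. Of 216 list tests 112 were called, 85 with an estimated correlation and 134 with the directional fry test. The replicate block is the dye orientation on the ratio arrays and the replicate number on the RNAi arrays. For lists it was run on the ratio arrays only, and 110 tests were called with the RNAi lists left unblocked. The median, the mean and the test of a list were not all of one sign in 27 of the 216, and 0 of these were called.

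Replicate numbers were tested for pairing. On the RNAi arrays 5 of 13 pairs with the same number deviated together at r over 0.1 (range -0.25 to 0.44), and 9 of 14 arrays correlated best with their own number. Of the 5, 4 join vector and Nanog RNAi arrays (r = 0.17, 0.20, 0.44 and 0.39), which may therefore be paired. The main fit leaves the number out, and with it as a block Nanog RNAi gave 8255 calls. On the ratio arrays the number is the dye orientation (the sample in Cy3 or Cy5), and deviations of the same number correlated at r = 0.51 to 0.92 in all 36 pairs of groups. Different groups correlated at a median r of 0.67 in the same orientation and 0.25 in the opposite one. The dye term is therefore given beside each count, and it raised every count of probes. Arrays within RNAi groups correlated at 0.990 to 0.997. Labels do not say whether swapped arrays hold separate cultures. Their p values measure spread between the 2 arrays of a treatment and day, which without the dye term includes the dye effect. Spread between days is left out of the standard errors. H19 with RA, for example, is given as 4.50 ± 0.14 but has an SD of 1.67 over its 6 arrays. A ratio against 0 also leaves out the spread of untreated cells.

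Alternatives run were the 2-group fit, leaving out each array, splitting the vector arrays, averaging each dye pair with treatment and day as terms, trended or robust eBayes, array weights, the mean of a gene's probe sets, the replicate block, a filter on dim probe sets, a change of at least 1 log2, complete probes only, and quantile, scale and median normalization. A pseudocount of 16 did not apply to log2 values and was not run, and median centring leaves ratio arrays with a median of 0 as they are. No scaling moved the median change of all genes by 0.1 log2 or more. The fits were checked on simulated data with known changes in 66 or 67 probes of each size. That is far fewer than were called in the data for Pou5f1 RNAi or RA over days 2 to 6. The adjusted p depends on the number of changed probes, so the shares hold for few changes only. For Pou5f1 RNAi 67.2% of changes of 0.5, 98.5% of 1 and 100% of 2 log2 were called. For RA over days 2 to 6 the shares were 23.9%, 73.1% and 97.0%, and 73.1%, 98.5% and 100% with the dye term, while day 6 against day 2 with RA called 2.99% of changes of 1 and 42.4% of 2 log2, and 52.2% and 89.4% with the dye term. A list shifted by 0.5 was recovered in 20 of 20 draws, and 1 of 340 unshifted lists was called. The simulated genes varied independently, so these draws cannot show how often the preset correlation calls unshifted lists of correlated genes. The number of arrays limits precision. Arrays carry no calls of presence here, and changes of dim genes are compressed.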

Results

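Gene expression was measured in mouse E14 embryonic stem (ES) cells after RNA interference (RNAi) against Pou5f1, which encodes Oct4, or against Nanog, and in E14 cells made to differentiate with retinoic acid (RA), dimethyl sulfoxide (DMSO) or hexamethylene bisacetamide (HMBA). The RNAi arrays comprise 5 from cells with empty vector, 5 with Nanog RNAi and 4 with Pou5f1 RNAi, each from cells transfected with a pSUPER-puro plasmid and kept in 1 µg/ml puromycin for 3 days from 24 h on. Those levels are log2 values of 45037 probe sets. The differentiation arrays carry 2 colours, and each gives the log ratio of treated to untreated E14 cells for 16657 probes that could be tested. They cover 0.1 µM RA, 1% DMSO and 3 mM HMBA on days 2, 4 and 6, with 2 arrays of opposite dye orientation per treatment and day, so 6 arrays per treatment. The base of those log ratios is not given in the sources used here and was taken as 2. Changes are printed in log2 as the difference ± its standard error. On the differentiation arrays that error comes from the 2 arrays of each treatment and day and leaves out the spread between days.

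What does the cell lose and gain when Pou5f1 is knocked down? Pou5f1 itself fell from 11.42 ± 0.089 in vector cells (mean ± SD, n = 5) to 9.03 ± 0.22 (n = 4), a change of -2.38 ± 0.10 (adjusted p = 1.1e-13). Nanog fell by 1.40 ± 0.09 (adjusted p = 3.4e-11). Rhox6, a homeobox gene of the placenta and germ line, rose most, by 7.29 ± 0.15, a fold of 156, followed by Krt8 (6.36 ± 0.10), Igf2 (6.32 ± 0.09), Krt7 (6.15 ± 0.19), Rhox9 (6.03 ± 0.13) and Krt18 (5.90 ± 0.11). The placental genes Nrk (5.84 ± 0.17) and Plac1 (5.65 ± 0.14) rose too, as did Pmp22 (5.54 ± 0.09) and Mbnl3 (5.47 ± 0.11). The deepest falls were Aass (-4.50 ± 0.10), Otx2 (-4.47 ± 0.15), Ina (-3.95 ± 0.10), Enox1 (-3.77 ± 0.11) and Trh (-3.64 ± 0.09). Next came Cubn (-3.56 ± 0.13), Zic5 (-3.52 ± 0.10), Socs2 (-3.45 ± 0.12), Gbx2 (-3.37 ± 0.13) and Nr0b1 (-3.35 ± 0.09). Otx2 and Zic5 mark the epiblast, the tissue that forms the embryo proper. In all, 14240 probe sets of 8258 genes were called, 7228 higher and 7012 lower, of which 2687 changed by at least 1 log2.

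The 18 gene lists tell which programmes these genes belong to. Counts are of called members, and where adjustment over the list alone gives other counts, these follow. Among pluripotency genes 29 of 33 fell and 1 rose, list alone 29 and 2 (adjusted p = 3.9e-19). The smallest p values were those of Nr0b1, Tdgf1 (-2.85 ± 0.09), Fgf4 (-3.12 ± 0.11) and Eras (-2.48 ± 0.09). The exception, Tbx3 (0.77 ± 0.08), and Sox2 (-1.72 ± 0.08) are named because their values had been seen. Among trophectoderm genes 23 of 25 rose and 1 fell (adjusted p = 2.5e-21), led by Krt8, Krt18, Rhox6 and Rhox9. Loss of Oct4 is known to turn ES cells towards trophectoderm. Cdx2, a member of this list chosen after its values were seen, rose by 2.34 ± 0.11 (adjusted p = 8.3e-13). For the epiblast list 13 of 19 fell and 1 rose, list alone 14 and 1 (adjusted p = 6.6e-08), with Etv5 (-2.70 ± 0.07), Zic5, Otx2 and Dnmt3l (-1.76 ± 0.07) first. Fibroblast and smooth muscle genes went up, 10 of 23 rose and 5 fell, list alone 10 and 6 (adjusted p = 0.018), led by Tagln (5.43 ± 0.10), Acta2 (3.34 ± 0.11), S100a6 (2.46 ± 0.10) and Timp3 (1.90 ± 0.11). The neural list went down, 9 of 27 fell and 3 rose (adjusted p = 0.026). Its leading genes Stmn2 (-3.19 ± 0.10), Neurod1 (-2.71 ± 0.13) and Gap43 (-1.94 ± 0.12) fell while Irx3 (3.65 ± 0.09) rose. The calls of these lists were kept with an estimated correlation between genes (adjusted p at most 0.021).

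A further group of lists was called with the preset correlation but not with an estimated one. The p53 response went up, 13 of 20 rose and 3 fell (adjusted p = 0.00034; adjusted p = 0.21 with an estimated correlation), with Perp (2.37 ± 0.09), Btg2 (2.02 ± 0.08), Phlda3 (1.29 ± 0.09) and Cdkn1a (1.54 ± 0.11). Imprinted genes also went up, 11 of 21 rose and 4 fell, list alone 12 and 4 (adjusted p = 0.0054; adjusted p = 0.21 with an estimated correlation). After Igf2 came Cdkn1c (4.04 ± 0.09), Sgce (2.96 ± 0.09) and Peg3 (2.25 ± 0.09). Germ cell and 2-cell stage genes followed, 10 of 19 rose and 3 fell, list alone 11 and 3 (adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation), with Taf7l (1.74 ± 0.12) and Slc25a31 (1.29 ± 0.11) first. Cell cycle genes went down, 22 of 31 fell and 2 rose, list alone 22 and 3 (adjusted p = 0.00016, and adjusted p = 0.36 with an estimated correlation), by small amounts. Examples are Mcm2 (-0.85 ± 0.07), Bub1 (-0.94 ± 0.08) and Mcm6 (-0.79 ± 0.07), while Ccne2 (1.02 ± 0.09) rose. Polycomb and chromatin genes went down, 14 of 25 fell and 4 rose, list alone 16 and 4 (adjusted p = 9.3e-05, and adjusted p = 0.088 with an estimated correlation), with Tet1 (-2.22 ± 0.08), Kdm4c (-1.76 ± 0.07), Kdm3a (-1.27 ± 0.08) and Tet2 (-1.54 ± 0.10).

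The remaining lists were not called after Pou5f1 RNAi. Nodal and BMP signalling held opposite changes, 6 of 20 fell and 7 rose, list alone 7 and 7 (adjusted p = 0.62). There Lefty1 (-2.75 ± 0.10), Gdf3 (-2.35 ± 0.09) and Nodal (-1.99 ± 0.08) fell and Msx2 (3.31 ± 0.14) rose. Primitive endoderm was split too, 12 of 29 fell and 9 rose, list alone 14 and 9 (adjusted p = 0.62). Glycolysis and hypoxia came close to a call, 13 of 22 fell and 4 rose (adjusted p = 0.063). The others, with genes that rose, genes that fell and adjusted p, were primitive streak and mesoderm (3 and 4, 0.67), retinoid response (4 and 6, 0.98) and interferon response (7 and 3, 0.56). To them belong cholesterol synthesis (4 and 8, 0.34) and unfolded protein and amino acid stress (8 and 10, 0.62). In the streak and retinoid lists the median was negative and the mean positive.

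**Figure D1:**
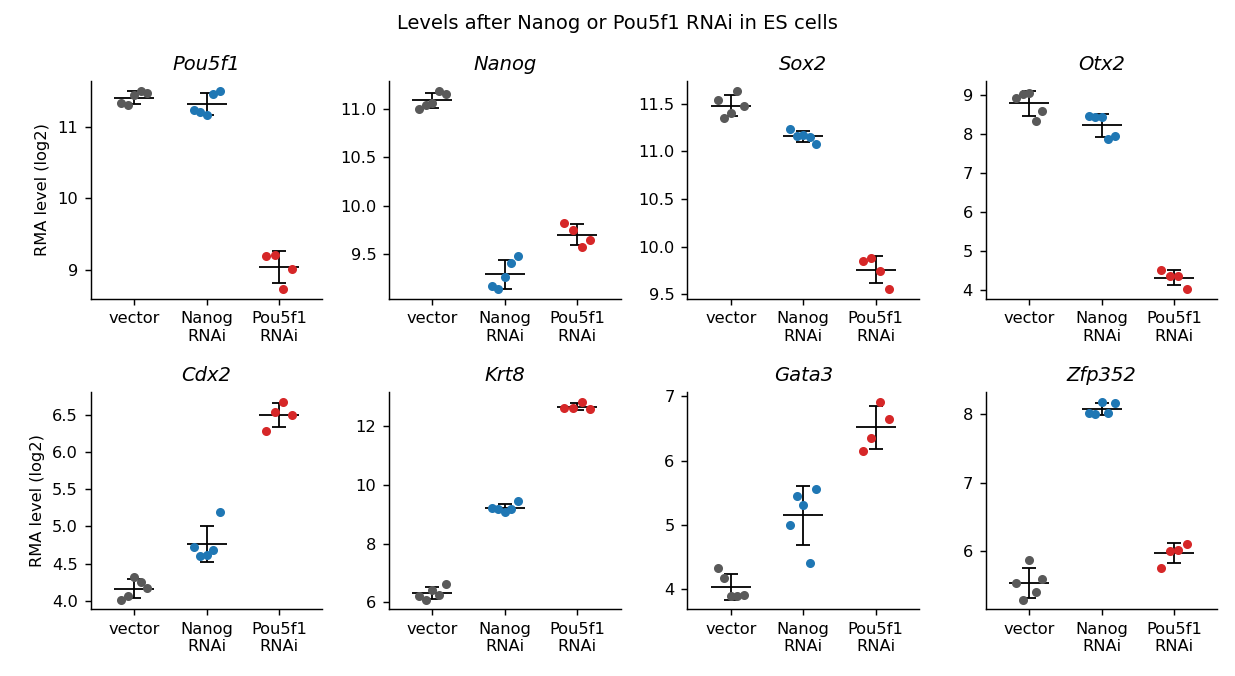
RMA level (log2) of 8 genes, some picked after their values were seen, on each array (points) with mean ± SD (bars) for vector (n = 5), Nanog RNAi (n = 5) and Pou5f1 RNAi (n = 4). Krt8 stood at 6.32 ± 0.20 in vector, 9.22 ± 0.14 in Nanog RNAi and 12.68 ± 0.11 in Pou5f1 RNAi cells, while Zfp352 was highest after Nanog RNAi (8.07 ± 0.089).

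Which of these changes follow when Nanog falls and Pou5f1 does not? In Nanog RNAi cells Nanog changed by -1.81 ± 0.08 (adjusted p = 2.1e-12, 5 against 5 arrays), whereas Pou5f1 changed by -0.10 ± 0.10 (adjusted p = 0.61). Fgfbp1, a binding protein of fibroblast growth factors, rose most, by 3.78 ± 0.10, followed by Vgll3 (3.14 ± 0.09), Krt8 (2.90 ± 0.10), Ccn2 (2.87 ± 0.07), Pramel18 (2.59 ± 0.10) and Anxa3 (2.59 ± 0.12). Next came Zfp352 (2.53 ± 0.10), a gene of the 2-cell embryo, Dst (2.50 ± 0.13), S100a6 (2.47 ± 0.10) and Mep1b (2.44 ± 0.09). The largest falls were Fxyd6 (-2.67 ± 0.11), A2m (-2.41 ± 0.13), the hedgehog effector Gli2 (-2.19 ± 0.12), Pfkp (-2.01 ± 0.15) and Lrrc34 (-1.93 ± 0.11). After Nanog followed Bhlhe40 (-1.80 ± 0.10), Inhbb (-1.80 ± 0.11), Marcks (-1.75 ± 0.09) and Prelid2 (-1.75 ± 0.09). In total 7017 probe sets of 4663 genes were called, 3963 higher and 3054 lower, and 493 of them changed by at least 1 log2.

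The trophectoderm list went up here too, though less, 17 of 25 rose and 0 fell, list alone 19 and 1 (adjusted p = 3.4e-12), with Krt18 (2.33 ± 0.10), Rhox6 (1.56 ± 0.14) and Ascl2 (1.08 ± 0.10) after Krt8. Cdx2, again chosen after its values were seen, rose by 0.60 ± 0.11. The p53 response went up, 14 of 20 rose and 0 fell, list alone 15 and 0 (adjusted p = 3.4e-12). It was led by Perp (2.22 ± 0.08), Pmaip1 (1.74 ± 0.07), Ddit4l (1.03 ± 0.08) and Phlda3 (1.07 ± 0.08). Among genes of glycolysis and hypoxia 16 of 22 fell and 1 rose, list alone 17 and 2 (adjusted p = 3.4e-12), with Bnip3 (-1.75 ± 0.07), Pfkp, Aldoc (-1.61 ± 0.11) and Tpi1 (-1.02 ± 0.07) in front. Imprinted genes went up, 11 of 21 rose and 0 fell, list alone 13 and 0 (adjusted p = 4.3e-09), as Igf2 (2.37 ± 0.08), Plagl1 (1.24 ± 0.08), Cdkn1c (1.35 ± 0.09) and Sgce (1.06 ± 0.08) show. These 4 lists kept their call with an estimated correlation (adjusted p at most 0.0072).

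Other calls after Nanog RNAi rested on the preset correlation. Cholesterol synthesis went down, 10 of 17 fell and 0 rose (adjusted p = 1.6e-06, and adjusted p = 0.13 with an estimated correlation), including Idi1 (-1.20 ± 0.08), Msmo1 (-0.93 ± 0.10) and Fdps (-0.67 ± 0.08). Germ cell and 2-cell stage genes went up, 10 of 19 rose and 3 fell, list alone 11 and 3 (adjusted p = 5.2e-05, and adjusted p = 0.073 with an estimated correlation). Beside Zfp352 they include Tcstv1 (1.54 ± 0.11), Tcstv3 (1.86 ± 0.14) and Stk31 (1.32 ± 0.10). Nodal and BMP signalling went up, 7 of 20 rose and 4 fell, list alone 8 and 4 (adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation). Its first genes were the BMP targets Id3 (2.14 ± 0.09), Id1 (1.61 ± 0.08) and Id2 (1.45 ± 0.09), then Nodal (1.01 ± 0.07). Nanog loss is known to favour primitive endoderm, and that list went up, 10 of 29 rose and 3 fell, list alone 10 and 4 (adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation). Its rises were small, as in Serpinh1 (0.59 ± 0.07), Cited2 (0.62 ± 0.08), Sparc (0.59 ± 0.08) and Foxa2 (0.64 ± 0.09).

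Pluripotency genes went both ways after Nanog RNAi, 13 of 33 fell and 6 rose, list alone 14 and 6 (adjusted p = 0.0024, and adjusted p = 0.33 with an estimated correlation). Besides Nanog, Eras (-1.30 ± 0.08), Tcl1 (-1.43 ± 0.10) and Fgf4 (-1.42 ± 0.10) fell, while Gbx2 (1.03 ± 0.12) and Dppa3 (0.91 ± 0.08), chosen after their values were seen, rose. Polycomb and chromatin genes went down, 7 of 25 fell and 0 rose (adjusted p = 0.0018, and adjusted p = 0.18 with an estimated correlation), among them Kdm5b (-0.67 ± 0.07) and Rnf2 (-0.63 ± 0.07). Not called (rose and fell, adjusted p) were epiblast (5 and 8, 0.48), primitive streak and mesoderm (4 and 2, 0.62), neural (5 and 5, 0.82) and retinoid response (3 and 2, 0.91). The rest were fibroblast and smooth muscle (4 and 4, 0.68), interferon response (1 and 2, 0.82), cell cycle (2 and 5, 0.82) and unfolded protein and amino acid stress (6 and 5, 0.82). Within the epiblast list Zic5 (-1.72 ± 0.09) fell and Igfbp3 (1.42 ± 0.09) rose. The retinoid list had a negative median and a positive mean.

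**Figure D2:**
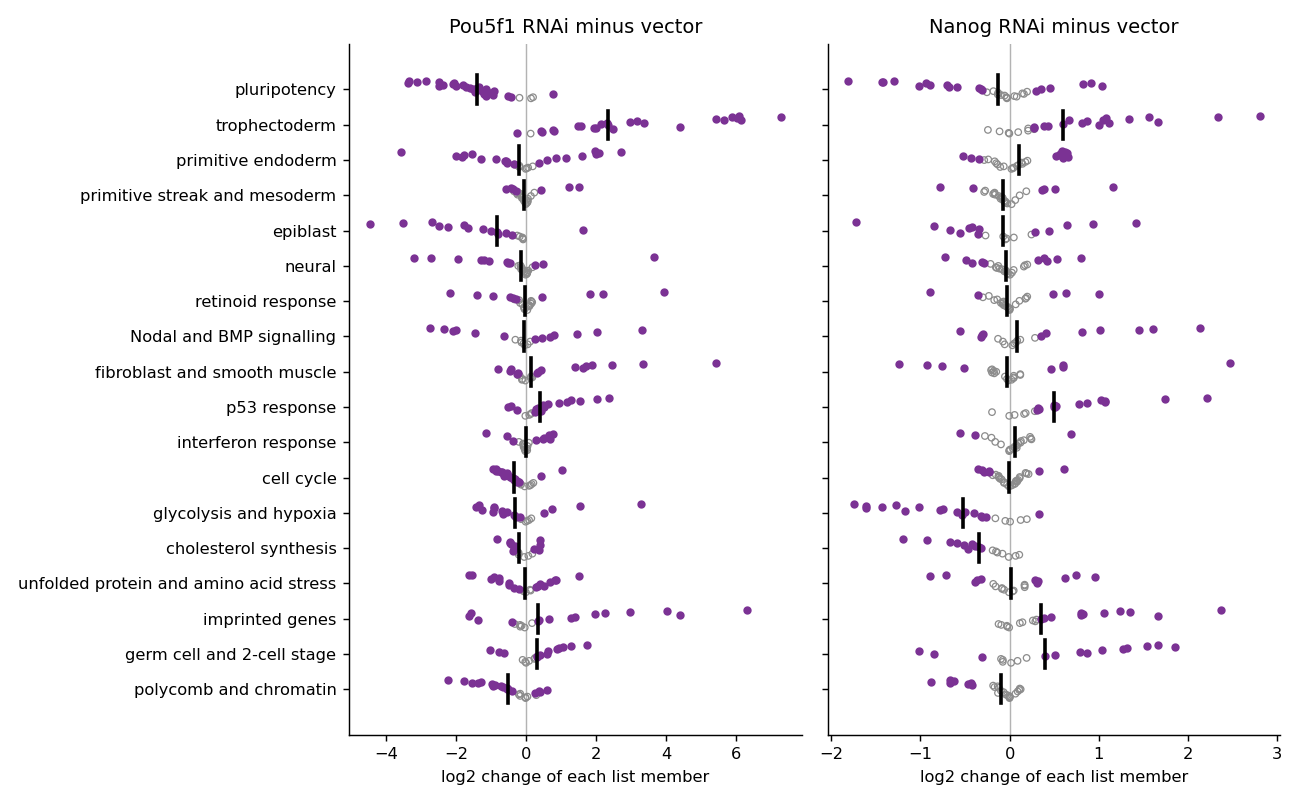
Log2 change of each measured member of the 18 gene lists in Pou5f1 RNAi (n = 4) and Nanog RNAi (n = 5) against vector (n = 5), with filled points for called genes, open points for the others and a bar at the median; the horizontal ranges differ. The trophectoderm median was 2.34 after Pou5f1 RNAi and 0.60 after Nanog RNAi, and that of glycolysis and hypoxia -0.30 and -0.52.

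How do the knockdowns differ from each other? Between Pou5f1 RNAi (n = 4) and Nanog RNAi (n = 5) 13282 probe sets of 7851 genes were called, 6740 higher and 6542 lower after Pou5f1 RNAi, and 2382 differed by at least 1 log2. Pou5f1 was lower by 2.29 ± 0.10 (adjusted p = 2.9e-13) and Nanog higher by 0.41 ± 0.09 (adjusted p = 0.00066). Highest over Nanog RNAi after Pou5f1 RNAi were Rhox6 (5.72 ± 0.15), Rhox9 (5.17 ± 0.13), Krt7 (5.14 ± 0.19), Pmp22 (5.08 ± 0.09) and Tagln (4.96 ± 0.10). Further ones were Nrk (4.80 ± 0.15), Krt19 (4.61 ± 0.13), Plac1 (4.31 ± 0.14), Acta1 (4.14 ± 0.09) and Gsn (4.07 ± 0.15). Lower were Aass (-4.64 ± 0.10), Gbx2 (-4.40 ± 0.13), Otx2 (-3.91 ± 0.15), Ina (-3.75 ± 0.10), Apela (-3.74 ± 0.09), then Lpar4 (-3.73 ± 0.09), Ccno (-3.57 ± 0.15), Enox1 (-3.56 ± 0.11), Spink1 (-3.53 ± 0.13) and Coch (-3.53 ± 0.12).

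Pluripotency genes were lower after Pou5f1 RNAi than after Nanog RNAi, where 29 of 33 were lower and 2 higher, list alone 30 and 3 (adjusted p = 1.6e-17). In front were Gbx2, Dppa3 (-2.92 ± 0.09), Tdgf1 (-2.53 ± 0.09) and L1td1 (-2.14 ± 0.08). Of trophectoderm genes 22 of 25 were higher and 1 lower (adjusted p = 1.2e-18), and of epiblast genes 13 of 19 were lower and 2 higher (adjusted p = 1.2e-07). Fibroblast and smooth muscle genes were higher (adjusted p = 0.0046) and neural genes lower (adjusted p = 0.023). These calls held with an estimated correlation (adjusted p at most 0.014). Of the genes of glycolysis and hypoxia 12 of 22 were higher and 3 lower (adjusted p = 0.0055, and adjusted p = 0.36 with an estimated correlation). Among them were Ndrg1 (3.10 ± 0.09), Bnip3 (1.47 ± 0.08), Hk1 (1.60 ± 0.11) and Tpi1 (1.06 ± 0.08). The calls of the cell cycle list (lower, adjusted p = 0.36 with an estimated correlation), the polycomb and chromatin list (lower, adjusted p = 0.30 with an estimated correlation) and cholesterol synthesis (higher, adjusted p = 0.57 with an estimated correlation) were lost as well. Nodal and BMP signalling was not called (adjusted p = 0.069), although Nodal (-3.0 ± 0.08) and Lefty1 (-2.86 ± 0.10) were far lower. The p53 response was not called (4 of 20 were higher and 5 lower, list alone 5 and 5, adjusted p = 0.94), and its median and mean had opposite signs, as had those of the retinoid list.

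Genes called the same way in both knockdowns numbered 2240 of 18194, with 1234 higher and 1006 lower, and 547 were called in opposite directions. The 2 comparisons share their vector arrays. No group held RNAi against an unrelated target, so a general response to RNAi was not tested. When the vector arrays were split so that each knockdown had its own, in 20 ways, 1297 to 1853 genes still went the same way (median 1564). Calls independent of each other would give 453 higher and 311 lower with shared vector arrays. With split vector arrays they would give a median of 305.5 higher and 208 lower. The changes correlated across genes at r = 0.43, and at 0.33 to 0.41 (median 0.38) when each knockdown had its own vector arrays. In 100 simulated sets with shared vector arrays and no effect r was 0.47, though the covariance was 0.0048, against 0.082 in the data. With a change of at least 1 log2 in both, 132 genes went the same way.

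What happens when the same cells differentiate with RA? Averaged over days 2 to 6 (n = 6 arrays) 4182 probes differed from untreated cells, 2439 higher and 1743 lower, and 8204 when dye orientation was a term of the fit. Pou5f1 fell by 1.93 ± 0.11 (adjusted p = 1.5e-07) whereas the change of Nanog (-0.47 ± 0.16) was not called (adjusted p = 0.052; 2.3e-05 with dye orientation as a term). Genes ranked by size with a treatment are those with a value of one sign on all 6 arrays. The imprinted transcript H19 rose most, by 4.50 ± 0.14, followed by Hmga2 (3.92 ± 0.31), Mest (3.68 ± 0.19), Col4a1 (3.54 ± 0.09), Tcstv1 (3.41 ± 0.15) and Acta2 (3.35 ± 0.09). Then came Smim7 (3.32 ± 0.10), Usp17la (3.26 ± 0.12), Nuak1 (3.24 ± 0.19) and Col1a2 (3.22 ± 0.10). The largest falls were Malat1 (-4.07 ± 0.11), Nr0b1 (-3.49 ± 0.17), Trh (-3.19 ± 0.14), Ache (-2.69 ± 0.13), Tdgf1 (-2.66 ± 0.27), then Il13ra2 (-2.49 ± 0.10), Zfp819 (-2.45 ± 0.10), Sycp3 (-2.44 ± 0.22), Tet1 (-2.40 ± 0.08) and Otx2 (-2.33 ± 0.09). The falls of Malat1 and Ache rest on 1 probe each, since other probes of Malat1 changed by -0.73 and -0.67 and other probes of Ache by 0.20 and 0.09.

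RA lowered pluripotency genes, 22 of 30 fell and 0 rose, list alone 24 and 1 (adjusted p = 3.8e-15), led by Fgf4 (-2.22 ± 0.09), Pou5f1, Nr0b1 and Nr5a2 (-1.87 ± 0.12). Retinoid response genes went up, 11 of 18 rose and 1 fell, list alone 12 and 1 (adjusted p = 1.0e-05). Those with the smallest p were Crabp1 (2.69 ± 0.09), which binds RA in the cytoplasm, Stra8 (2.56 ± 0.16), Crabp2 (2.55 ± 0.15) and Tgm2 (1.33 ± 0.09). Trophectoderm genes went up, 14 of 20 rose and 1 fell (adjusted p = 1.0e-07), with Krt8 (3.01 ± 0.09), Krt7 (2.49 ± 0.09), Krt19 (2.14 ± 0.10) and Rhox9 (2.28 ± 0.11). Primitive endoderm genes went up beside them, 12 of 23 rose and 2 fell, list alone 14 and 2 (adjusted p = 1.6e-05), with Col4a1, Col4a2 (2.39 ± 0.12), Sparc (2.33 ± 0.12) and Serpinh1 (2.07 ± 0.11). So did fibroblast and smooth muscle genes, 12 of 18 rose and 0 fell (adjusted p = 1.3e-08). Next to Acta2 and Col1a2 these include Loxl2 (2.21 ± 0.08) and Igfbp4 (2.51 ± 0.09). Imprinted genes went up, 13 of 20 rose and 2 fell (adjusted p = 5.1e-08), with Cdkn1c (2.54 ± 0.09), H19, Peg3 (3.08 ± 0.13) and Grb10 (2.19 ± 0.10). Cholesterol synthesis went up as well, 9 of 16 rose and 0 fell, list alone 10 and 0 (adjusted p = 8.7e-05), as in Sc5d (1.26 ± 0.11) and Dhcr7 (0.83 ± 0.08). These 7 calls were kept with an estimated correlation (adjusted p at most 0.0010) and with dye orientation as a term (at most 4.0e-05).

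Epiblast genes went down with RA, 8 of 18 fell and 4 rose (adjusted p = 0.044). So did polycomb and chromatin genes, 7 of 21 fell and 3 rose, list alone 8 and 3 (adjusted p = 0.044). Both calls were lost with an estimated correlation (adjusted p = 0.18 and 0.26), and the epiblast call with dye orientation as a term (adjusted p = 0.081). Otx2 and Etv5 (-1.52 ± 0.12) fell while Sall2 (1.14 ± 0.12) rose. Not called (rose and fell, adjusted p) were Nodal and BMP signalling (6 and 2, 0.071), unfolded protein and amino acid stress (0 and 4, 0.077), primitive streak and mesoderm (7 and 1, 0.11) and glycolysis and hypoxia (3 and 5, 0.18). Nor were p53 response (7 and 0, 0.19), interferon response (0 and 3, 0.28), cell cycle (2 and 3, 0.36), neural (5 and 4, 0.76) and germ cell and 2-cell stage (2 and 3, 0.76).

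DMSO changed 2834 probes (n = 6 arrays), 1565 higher and 1269 lower, and 6838 with dye orientation as a term. Pou5f1 fell by 0.62 ± 0.11 (adjusted p = 0.0022) and Nanog by 1.55 ± 0.16 (adjusted p = 2.8e-05). Among genes with a value on all 6 arrays Ooep, a gene of the egg and early embryo, fell most, by 3.96 ± 0.09, followed by Zfp42 (-3.89 ± 0.30), also called Rex1, Dppa5a (-3.68 ± 0.11), Klf4 (-3.64 ± 0.32) and Morc1 (-3.35 ± 0.30). Behind them came Trh (-3.20 ± 0.14), Cyct (-3.13 ± 0.12), Dppa2 (-3.06 ± 0.16), Fbxo15 (-3.05 ± 0.11) and Hormad1 (-3.04 ± 0.27). Rises were smaller, in Gbp2b (2.41 ± 0.25), Car4 (2.23 ± 0.10), Amotl2 (2.14 ± 0.11), Pim2 (2.04 ± 0.09), Prickle1 (1.84 ± 0.15), Fgfbp1 (1.84 ± 0.16), Car2 (1.82 ± 0.34), Tpm1 (1.81 ± 0.23), Rhob (1.80 ± 0.09) and Flnc (1.79 ± 0.11). The second DMSO array of day 4 has values for 11257 probes, the fewest of the 18 arrays, and the 2 arrays of day 2 correlated at r = -0.01.

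Pluripotency genes went down with DMSO, 26 of 30 fell and 0 rose, list alone 27 and 1 (adjusted p = 7.4e-27), with Nr5a2 (-2.51 ± 0.12) and Fgf4 (-2.45 ± 0.10) after Dppa5a and Fbxo15. Interferon response genes went up, 7 of 15 rose and 0 fell (adjusted p = 0.0021), led by Irf1 (1.10 ± 0.09), Psmb8 (1.09 ± 0.11), Gbp2 (1.46 ± 0.16) and Oasl2 (0.70 ± 0.10). Germ cell and 2-cell stage genes went down, 7 of 15 fell and 0 rose (adjusted p = 8.7e-05), including Tex19.1 (-2.57 ± 0.14) and Tcstv1 (-1.67 ± 0.15). Cholesterol synthesis went up, 7 of 16 rose and 0 fell, list alone 8 and 0 (adjusted p = 0.00051), with Dhcr7 (0.71 ± 0.08) first. The unfolded protein and amino acid stress list went down, 7 of 21 fell and 0 rose (adjusted p = 0.025), with Cth (-1.56 ± 0.12) first. Fibroblast and smooth muscle genes went up, 7 of 18 rose and 2 fell (adjusted p = 0.042), with Col1a2 (1.47 ± 0.11) first. The p53 response went down (3 of 17 fell and 0 rose, list alone 3 and 1; adjusted p = 0.046), but not with dye orientation as a term (adjusted p = 0.10). Other calls were lost with an estimated correlation. They are primitive endoderm (5 of 23 rose and 1 fell, adjusted p = 0.12 with it) and imprinted genes (6 of 20 rose and 2 fell, list alone 8 and 2, adjusted p = 0.12). Polycomb and chromatin (7 of 21 fell and 3 rose, list alone 8 and 3, adjusted p = 0.23) is another. With dye orientation as a term primitive endoderm (adjusted p = 0.10) and imprinted genes (adjusted p = 0.12) were lost too.

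The trophectoderm list was not called with DMSO (4 rose and 3 fell, adjusted p = 0.67), and within it Krt8 (1.36 ± 0.09) rose and Tfap2c (-1.59 ± 0.10) fell. Also without a call (rose and fell, adjusted p) were epiblast (7 and 4, 0.21), primitive streak and mesoderm (4 and 1, 0.077), Nodal and BMP signalling (5 and 2, 0.21) and neural (3 and 3, 0.50). The rest were retinoid response (3 and 1, 0.50), cell cycle (1 and 0, 0.53) and glycolysis and hypoxia (0 and 4, 0.41), the last with a positive median and a negative mean.

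HMBA changed 4137 probes (n = 6 arrays), 2237 higher and 1900 lower, and 7964 with dye orientation as a term. It lowered Pou5f1 by 1.47 ± 0.11 (adjusted p = 1.6e-06) and Nanog by 1.40 ± 0.16 (adjusted p = 3.9e-05). Krt8 rose most, by 3.53 ± 0.09, then H19 (3.00 ± 0.14), Car4 (2.84 ± 0.10), Cntn3 (2.80 ± 0.16), Col1a2 (2.80 ± 0.10), Gata3 (2.73 ± 0.17), Amotl2 (2.73 ± 0.11), Nuak1 (2.72 ± 0.19), Peg10 (2.69 ± 0.21) and Krt19 (2.62 ± 0.10). Nr0b1 fell by 4.43 ± 0.17, ahead of Trh (-3.65 ± 0.14), Tdgf1 (-3.29 ± 0.27), Morc1 (-3.25 ± 0.30), Tet1 (-3.24 ± 0.08), Ooep (-3.09 ± 0.09), Zfp42 (-3.05 ± 0.30), Fbxo15 (-2.98 ± 0.11), Cyct (-2.88 ± 0.12) and Aass (-2.82 ± 0.32).

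HMBA lowered pluripotency genes, 25 of 30 fell and 0 rose, list alone 27 and 1 (adjusted p = 1.6e-18). It raised trophectoderm genes, 12 of 20 rose and 1 fell, list alone 13 and 1 (adjusted p = 1.8e-07), with Krt7 (2.16 ± 0.09) after Krt8 and Krt19. Imprinted genes went up, 14 of 20 rose and 1 fell (adjusted p = 2.6e-07), led by Nnat (2.21 ± 0.09), H19, Cdkn1c (1.61 ± 0.09) and Peg3 (2.10 ± 0.13). Cholesterol synthesis went up too, 10 of 16 rose and 0 fell (adjusted p = 2.0e-05). The same holds for fibroblast and smooth muscle genes, 8 of 18 rose and 0 fell (adjusted p = 2.3e-05). As with DMSO, unfolded protein and amino acid stress genes went down, 8 of 21 fell and 0 rose, list alone 9 and 0 (adjusted p = 0.00012), for instance Cth (-2.10 ± 0.12). Germ cell and 2-cell stage genes went down as well, 7 of 15 fell and 0 rose (adjusted p = 5.9e-05), for instance Tex19.1 (-1.67 ± 0.14). Primitive endoderm went up, 7 of 23 rose and 2 fell, list alone 8 and 2 (adjusted p = 0.041), and the epiblast list down, 8 of 18 fell and 2 rose, list alone 9 and 2 (adjusted p = 0.020). Both were lost with an estimated correlation (adjusted p = 0.13 and 0.13). Within the epiblast list Otx2 (-2.08 ± 0.09) and Etv5 (-1.62 ± 0.12) fell while Cldn6 (1.99 ± 0.16) rose. Polycomb and chromatin genes were not called (adjusted p = 0.099) except with dye orientation as a term (adjusted p = 0.039).

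Lists without a call under HMBA (rose and fell, adjusted p) were retinoid response (6 and 2, 0.20), glycolysis and hypoxia (2 and 5, 0.28), p53 response (4 and 5, 0.42) and neural (4 and 3, 0.66). The others were Nodal and BMP signalling (6 and 4, 0.66), interferon response (2 and 1, 0.66), cell cycle (2 and 5, 0.71) and primitive streak and mesoderm (2 and 2, 0.71). Nodal and BMP signalling and the streak list had negative medians and positive means.

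**Figure D3:**
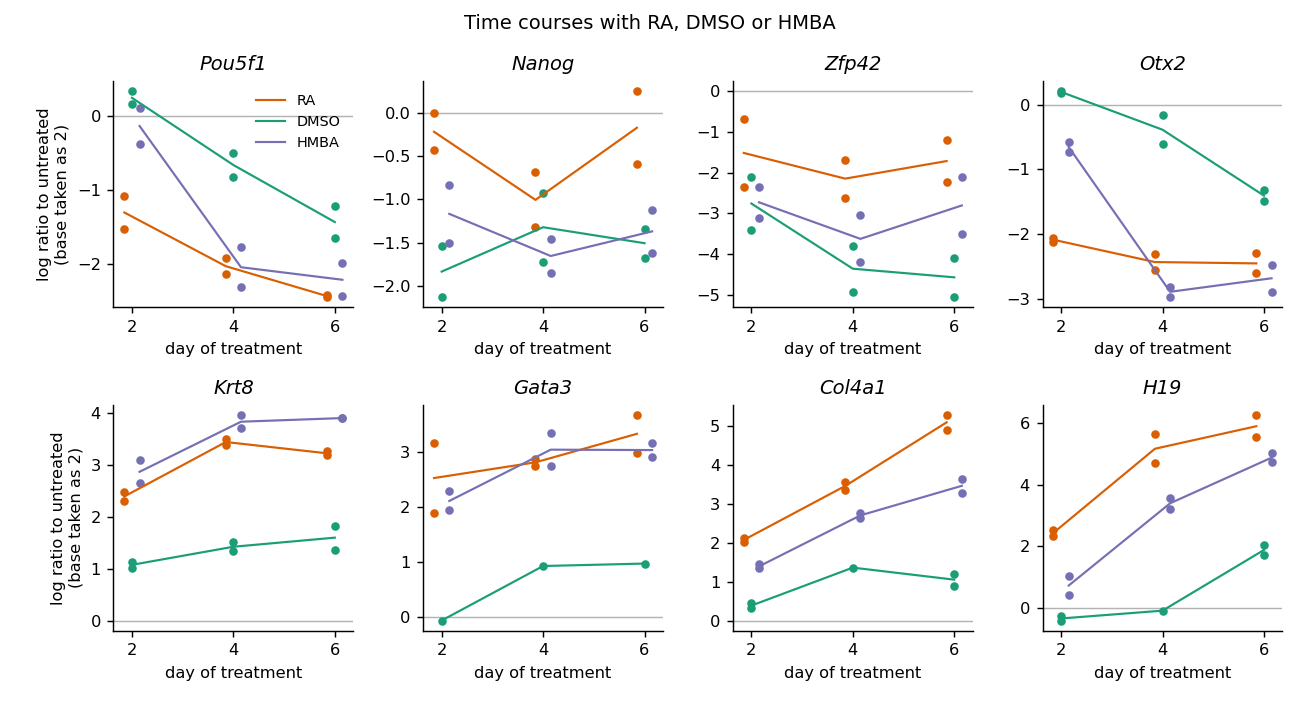
Log ratio to untreated cells (base taken as 2) of 8 genes, some picked after their values were seen, on days 2, 4 and 6 of RA, DMSO or HMBA, with 2 arrays per day (points) and their means (lines). On day 2 the Pou5f1 mean was -1.31 with RA, 0.24 with DMSO and -0.14 with HMBA, and on day 6 -2.44, -1.44 and -2.22.

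Which genes change from day 2 to day 6? With 2 arrays per day 182 probes were called with RA (119 higher, 63 lower), 159 with DMSO (81 and 78) and 246 with HMBA (113 and 133). With dye orientation as a term there were 1774, 1647 and 1670. Between these days Pou5f1 fell with DMSO by 1.68 ± 0.28 (adjusted p = 0.013) and with HMBA by 2.08 ± 0.28 (adjusted p = 0.0023). With RA its change of -1.13 ± 0.28 was not called (adjusted p = 0.092), except with dye orientation as a term (adjusted p = 0.0040). Nanog had no called change, at 0.05 ± 0.40 with RA, 0.33 ± 0.40 with DMSO and -0.20 ± 0.40 with HMBA. In RA Rhox6 (3.89 ± 0.41), Lama1 (3.47 ± 0.30), H19 (3.46 ± 0.35), Rhox9 (3.36 ± 0.28) and Nxf7 (3.14 ± 0.52) rose. The falls were Trh (-3.57 ± 0.34), Gbx2 (-3.52 ± 0.72), Csn3 (-2.85 ± 0.53), Lefty1 (-2.54 ± 0.28) and Ina (-2.51 ± 0.26). In HMBA the rises were Rhox6 (4.48 ± 0.41), H19 (4.15 ± 0.35), Nxf7 (3.69, with a value missing on day 2), Smim7 (3.57 ± 0.25) and Rhox9 (3.50 ± 0.28). Falls were seen in Pim2 (-4.0 ± 0.23), Trh (-3.71 ± 0.34), Noct (-2.89 ± 0.46), Gstt2 (-2.66 ± 0.29) and Apoe (-2.64 ± 0.30). DMSO raised Sprr2i (3.64 ± 0.42), Defa31 (3.20 ± 0.50), Pik3ip1 (3.02 ± 0.21), Sprr2b (2.43 ± 0.37) and Slc2a3 (2.38 ± 0.29). It lowered Trh (-3.88 ± 0.34), Dppa2 (-3.10 ± 0.40), Nefh (-2.71 ± 0.48), Dnmt3b (-2.57 ± 0.50) and Dnmt3l (-2.55 ± 0.41).

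From day 2 to day 6 trophectoderm genes went up with RA, 6 of 20 rose and 0 fell, list alone 11 and 0 (adjusted p = 2.1e-12), with Krt19 (2.17 ± 0.24) among the first. They did so too with HMBA, 10 of 20 rose and 0 fell, list alone 12 and 0 (adjusted p = 8.9e-21), with Krt7 (2.64 ± 0.21) among the first. Primitive endoderm genes went up with RA (7 of 23 rose and 0 fell, list alone 10 and 1; adjusted p = 2.6e-09), led by Col4a1 (3.02 ± 0.22), Lama1 and Dab2 (2.71 ± 0.28). The epiblast list went down with RA, 1 of 18 fell and 0 rose, list alone 6 and 1 (adjusted p = 0.00019). Between these days it went down with DMSO too, 4 of 18 fell and 0 rose, list alone 6 and 0 (adjusted p = 5.4e-06), where Otx2 (-1.60 ± 0.23) led. With HMBA 5 of 18 fell and 0 rose, list alone 11 and 0 (adjusted p = 4.4e-14), again with Otx2 (-2.03 ± 0.23) first. Pluripotency genes went down with DMSO (6 of 30 fell and 0 rose, list alone 10 and 1; adjusted p = 1.9e-12) and RA (adjusted p = 0.00066), with Foxd3 (-1.97 ± 0.27) after Dppa2 in DMSO. The retinoid response list was called lower with RA (0 of 18 fell and 0 rose, list alone 1 and 0; adjusted p = 0.0015). The imprinted list as a whole went up with RA (adjusted p = 0.00022) and HMBA (adjusted p = 2.7e-07), where Cdkn1c (3.38 ± 0.22) led.

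Further calls with RA were glycolysis and hypoxia up (adjusted p = 0.00066), cholesterol synthesis up (adjusted p = 0.0050) and neural genes down (adjusted p = 0.015; adjusted p = 0.058 with an estimated correlation). With DMSO they were fibroblast and smooth muscle up (adjusted p = 0.00088), interferon response up (adjusted p = 0.00049), glycolysis and hypoxia up (adjusted p = 0.00014), and unfolded protein and amino acid stress down (adjusted p = 0.0018). Germ cell and 2-cell stage genes went down (adjusted p = 0.00034). Primitive endoderm (adjusted p = 0.0099) and Nodal and BMP signalling (adjusted p = 0.030) went up. With HMBA they were unfolded protein and amino acid stress down (adjusted p = 6.5e-05) and glycolysis and hypoxia up (adjusted p = 0.013; adjusted p = 0.051 with an estimated correlation).

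How do the inducers differ? RA and DMSO differed in 1031 probes, 618 higher and 413 lower with RA (3781 with dye orientation as a term). The means are of up to 6 arrays each, as some probes lack a value on some arrays (H19 has 5 with DMSO). Pou5f1 was lower with RA by 1.31 ± 0.16 (adjusted p = 0.00033) and Nanog higher by 1.09 ± 0.23 (adjusted p = 0.012). Higher with RA were Tcstv1 (5.08 ± 0.21), Usp17la (4.82 ± 0.18), H19 (4.02 ± 0.22), Mest (3.53 ± 0.26) and Rhox6 (3.26 ± 0.24). Lower were Malat1 (-4.65 ± 0.16), Pim2 (-4.0 ± 0.13), Ache (-3.24 ± 0.18), Il13ra2 (-2.92 ± 0.14) and Nts (-2.73 ± 0.20). With RA the trophectoderm list was higher, as 12 of 20 were higher and 0 lower, list alone 15 and 0 (adjusted p = 1.1e-14). Fibroblast and smooth muscle (adjusted p = 5.7e-13), imprinted (adjusted p = 2.2e-10) and retinoid genes (adjusted p = 1.4e-07) were higher, for example Acta2 (2.60 ± 0.13), Cdkn1c (2.83 ± 0.13) and Crabp1 (2.65 ± 0.13). Primitive endoderm genes were higher too (adjusted p = 3.3e-06), Col4a1 (2.61 ± 0.14) before the others. Of interferon genes 5 of 15 were lower and 0 higher (adjusted p = 3.6e-07), led by Irf1 (-1.59 ± 0.13). Of epiblast genes 7 of 18 were lower and 1 higher (adjusted p = 3.3e-06), led by Otx2 (-1.79 ± 0.13). The pluripotency list was higher with RA than with DMSO, as 11 of 30 were higher and 2 lower, list alone 15 and 2 (adjusted p = 1.7e-06). It was led by Dppa5a (2.46 ± 0.15), Fbxo15 (2.14 ± 0.15) and Dppa2 (2.72 ± 0.23), so Pou5f1 ran against its list. Germ cell and 2-cell stage genes (adjusted p = 7.0e-05), the p53 response (adjusted p = 0.00097) and Nodal and BMP signalling (adjusted p = 0.034) were higher too. The cell cycle list was lower (adjusted p = 0.049; adjusted p = 0.47 with an estimated correlation). All RA arrays lay beyond all DMSO arrays in 19 of the 21 named genes with a call, over the 3 days together. Most of these genes were named for their change in this comparison, which favours such separation.

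RA and HMBA differed in 546 probes (342 higher with RA, 204 lower; 2742 with dye orientation as a term). Nanog was higher with RA by 0.93 ± 0.23 (adjusted p = 0.047), and Pou5f1 was not called (-0.46 ± 0.16, adjusted p = 0.21) except with dye orientation as a term (adjusted p = 0.026). Higher with RA were Usp17la (5.05 ± 0.18), Tcstv1 (4.84 ± 0.21), Pde11a (3.09 ± 0.24), Wdr7 (2.84 ± 0.14) and Il11ra2 (2.78 ± 0.17). Lower were Malat1 (-4.97 ± 0.16), Ache (-3.52 ± 0.18), Il13ra2 (-2.71 ± 0.14), Nts (-2.33 ± 0.20) and Pim2 (-2.10 ± 0.13). The retinoid list was higher (5 of 18 were higher and 0 lower, list alone 9 and 0; adjusted p = 1.3e-07), with Crabp1 (2.31 ± 0.13) and Stra8 (2.71 ± 0.22) first. Fibroblast and smooth muscle (adjusted p = 4.9e-07), germ cell and 2-cell stage (adjusted p = 1.9e-06), primitive endoderm (adjusted p = 2.7e-05), pluripotency (adjusted p = 6.7e-05) and imprinted genes (adjusted p = 0.00016) were higher as well. The trophectoderm list was not called (2 of 20 were lower and 2 higher, list alone 3 and 2, adjusted p = 0.82). The p53 response (adjusted p = 0.0016), Nodal and BMP signalling (adjusted p = 0.0063) and unfolded protein and amino acid stress (adjusted p = 0.014) were higher. The interferon response was lower (adjusted p = 0.014). Of the 13 named genes with a call 11 had no overlap between RA and HMBA arrays, which their choice by size or p again favours. The streak list was higher (adjusted p = 0.042; adjusted p = 0.58 with an estimated correlation).

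DMSO and HMBA differed least, in 242 probes (81 higher with DMSO, 161 lower; 1608 with dye orientation as a term). Pou5f1 was higher with DMSO by 0.85 ± 0.16 (adjusted p = 0.022), and Nanog was not called (-0.16 ± 0.23). Higher with DMSO were Pim2 (1.91 ± 0.13), Fgf5 (1.74 ± 0.30), Slc27a2 (1.58 ± 0.24), Otx2 (1.55 ± 0.13) and Dll3 (1.43 ± 0.17). Lower were H19 (-2.52 ± 0.22), Phlda2 (-2.23 ± 0.17), Peg10 (-2.20 ± 0.29), Gsn (-2.19 ± 0.17) and Krt8 (-2.17 ± 0.13). Of trophectoderm genes 13 of 20 were lower and 0 higher, list alone 14 and 1 (adjusted p = 1.4e-25), led by Krt8. Imprinted (adjusted p = 4.8e-10) and fibroblast and smooth muscle genes (adjusted p = 6.0e-09) were lower with DMSO too, led by Cdkn1c (-1.90 ± 0.13) and S100a6 (-2.10 ± 0.13). Epiblast (4 of 18 were higher and 1 lower, list alone 11 and 2; adjusted p = 8.8e-09) and interferon genes (adjusted p = 2.7e-05) were higher, among them Irf1 (1.34 ± 0.13). The pluripotency list was called lower (adjusted p = 0.0095) with a median of -0.23, although 1 of 30 were lower and 2 higher, list alone 4 and 2. The unfolded protein and amino acid stress list was called higher (adjusted p = 0.021). The calls of cholesterol synthesis (lower, adjusted p = 0.067 with an estimated correlation) and primitive endoderm (lower, adjusted p = 0.12 with an estimated correlation) were lost. All DMSO arrays lay beyond all HMBA arrays in 5 of the 14 named genes with a call, which were chosen in the same way. The doses are not matched, so effects of the dose and of the compound cannot be told apart in these differences.

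Do the knockdown genes move during differentiation? The 2743 genes higher and 2553 lower after Pou5f1 RNAi, and the 1637 higher and 1209 lower after Nanog RNAi, were followed in each treatment. Of the 2743, 1125 rose and 73 fell with RA (median 0.33, adjusted p = 1.9e-22), 642 and 115 with DMSO (median 0.19, adjusted p = 1.9e-09) and 1127 and 92 with HMBA (median 0.33, adjusted p = 1.7e-25). Of the 2553, 634 fell and 190 rose with RA (adjusted p = 1.7e-12), 522 and 172 with DMSO (adjusted p = 3.0e-09) and 833 and 140 with HMBA (adjusted p = 7.9e-19). Of the 1637, 563 rose and 121 fell with RA (adjusted p = 3.4e-07), 328 and 165 with DMSO (adjusted p = 0.032; 0.29 with an estimated correlation) and 532 and 189 with HMBA (adjusted p = 2.3e-05). The 1209 went down (adjusted p = 0.00029, 0.013 and 2.3e-05), but not with an estimated correlation (adjusted p = 0.15, 0.29 and 0.096). Across 10995 genes Pou5f1 RNAi correlated with RA at r = 0.50, DMSO at 0.36 and HMBA at 0.56, and Nanog RNAi at 0.26, 0.14 and 0.25.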

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

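The tests of the 2-cell stage genes, of the order of the spiked controls, of the dye orientation of Malat1 and Ache and of random probe pairs were chosen only after the results had been seen, and the sorted order of the control identifiers after the control levels of 3 arrays had been seen.

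Identifiers and values of the 64 control probe sets on the RNAi arrays are likely sorted in different orders. As deposited, the CreX control reads 3.03, Gapdh 3.00 and beta-actin 7.15, and with the identifiers sorted by character code 12.0, 13.3 and 12.9. Sorted so, bioB, bioC, bioD and cre rise in the order of their spiked amounts on 14 of 14 arrays (0 as deposited), whereas the median correlation of the Gapdh and beta-actin controls with the other probe sets of these genes, the test written beforehand, was 0.279 (-0.033 as deposited) and leaves the question open. Gene probe sets out of order as well is unlikely, since 2 probe sets of one gene correlated at a median of 0.607 over 4978 genes, against 0.016 for shuffled pairs. With the sorted identifiers the 3' minus 5' difference of beta-actin was 0.307 ± 0.028 in vector, 0.252 ± 0.016 in Nanog RNAi and 0.117 ± 0.0069 in Pou5f1 RNAi arrays (mean ± SD; exact permutation p = 0.0079 for Pou5f1 RNAi and 0.016 for Nanog RNAi against vector, 0.024 each after adjustment). That of Gapdh was lower by 0.057 after Pou5f1 RNAi (adjusted p = 0.029) but not called after Nanog RNAi (0.027, adjusted p = 0.77, with replicate 5 at 0.345 and the others at 0.156 to 0.177), so RNA quality may differ by a small amount for Pou5f1 RNAi and is unclear for Nanog RNAi.

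Genes of the 2-cell embryo were higher after Nanog RNAi. From a list of such genes drawn up after members of 5 families had been seen, 17 of 19 were called higher, in 12 of 14 families, and in 7 of the 9 families not seen before, so the signal of 1 gene family shared between near-identical copies is unlikely to account for them. Nor could 1 array, as their median change of 1.66 stayed at 1.60 or above in each of 10 fits without an array. After Pou5f1 RNAi 8 of 19 were higher. With RA 4 of 9 were higher, in 3 families (1 of the 4 not seen before), and 1 was lower, too few to exclude that explanation there, while 3 were lower with DMSO, 4 with HMBA and 0 higher with either.

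Malat1 and Ache were both lower in RA than in DMSO, by 4.65 ± 0.16 and 3.24 ± 0.18, on probes numbered 1112605 and 1112604. Dye orientation is unlikely to be the cause, as each treatment and day holds both orientations. Within both (2 of 2) orientations each RA array lay below each DMSO array for both probes, a check chosen after the values were seen. Over 18 arrays, after each treatment's mean was taken away, their r was 0.815, above the threshold set beforehand for probes that read 1 transcript. That r is reached by 4.5% of 10000 random probe pairs, and their r of 0.535 with day and dye orientation taken away too by 16.6%. Whether both probes read 1 transcript therefore cannot be told. No other probe of these genes was called (most -1.06, adjusted p = 0.11, for one of Malat1). Whether probes with neighbouring numbers share signal stays open too, at r = 0.137 over 8892 such pairs.

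In 14 of 270 sets of values 1 array stood apart from its group, which is about the share of 1 in 20 groups that chance alone gives. Of these sets Pou5f1 RNAi replicate 3 accounted for 4. It read 12.8 for Krt8, 10.5 for Plac1, 11.5 for Tpi1 and 6.58 for Trh. Nanog RNAi replicate 5 read 5.19 for Cdx2, 9.71 for Krt18 and 0.345 for the 3' minus 5' difference of Gapdh, and replicate 4 read 7.41 for Lpar4 and 11.4 for Tdgf1. Vector arrays stood apart for Cited2 (8.37), Id3 (7.62), Kdm3a (9.96) and Krt7 (4.03), and Pou5f1 RNAi replicate 4 for Lefty1 (6.14). The change from day 2 to day 6 differed between RA and DMSO for 17 probes (326 with dye orientation as a term), among them those of Rhox9, Lama1 and Col4a1, chosen after their values were seen. Between RA and HMBA it differed for 5 probes (225 with that term), those of Crabp1, Me1, Lama1 and 2 without a gene name, all 5 named after their values were seen. Between DMSO and HMBA it differed for 33 probes (437 with that term). Control probe sets called higher numbered 3 after Pou5f1 RNAi and 3 after Nanog RNAi, and 3 were called lower in each. Between the knockdowns 6 were higher and 5 lower after Pou5f1 RNAi. Their identities are in doubt as above.

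Chance is unlikely to explain the calls of the RNAi comparisons. Of 100 splits of the same arrays, the real one included, 1 gave as many calls in each. The splits take the arrays as independent, although vector and Nanog RNAi arrays may be paired. For Pou5f1 RNAi the real split gave 14024 and the highest other 7067, for Nanog RNAi 6060 and 1, and for Pou5f1 against Nanog RNAi 14129 and 8040. Each split was fitted on the 2 groups compared alone, and on the ratio arrays without regard to day and on probes complete on all 18 arrays. These counts are therefore not those of the main fit (1031, 546 and 242 for the 3 pairs of treatments). RA against DMSO gave 521 and at most 8 otherwise (1 in 100). For RA against HMBA 2 of 100 splits gave as many (260, highest other 1034) and for DMSO against HMBA 3 (23, highest other 2184), but splits that call many follow the dye orientation, a technical structure, which called 5147, 4959 and 5701 probes among the arrays of the 3 pairs. Among splits balanced in dye the real one was the highest in each pair (highest other 8, 39 and 0), and so it was with a dye term (1437 against 246, 843 against 425, 233 against 0). These splits take all arrays as independent, and labels do not say whether swapped arrays hold separate cultures. If they do not, fewer splits are possible, so whether chance explains these differences cannot be told.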

How the results depend on the processing

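The fits without DMSO day 2 or day 4 and the dye term for lists were chosen after the results had been seen. Of 153 gene results on the RNAi arrays 153 stayed the same with array weights, quantile normalization and the replicate block, whose numbers pair the arrays in part at most (r over 0.1 in 5 of 13 pairs), and of 208 on the ratio arrays 204 did with dye orientation as a term and 4 became stronger. With dye pairs averaged and treatment and day as terms, 2 changes at once, 155 stayed the same, 7 were weaker and 2 stronger, and those of day 6 against day 2 were not run, since 1 value per day remains. Without 1 array, fits on ratio arrays gave 1375 gene results as before, 68 weaker, 1 stronger and 4 reversed. Scale normalization gave 200 the same, 7 weaker and 1 reversed. Where a value moved, the cause was not tested.

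A change of at least 1 log2 left 2687 calls for Pou5f1 RNAi, 493 for Nanog RNAi, 2382 between them, 132 shared genes, 804 for RA, 554 for DMSO, 816 for HMBA, 391 for RA against DMSO, 223 for RA against HMBA and 109 for DMSO against HMBA. The mean of a gene's probe sets gave 7674, 4138 and 7150 in the RNAi comparisons.

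Dye orientation as a term gave 8204 calls for RA, 6838 for DMSO, 7964 for HMBA, 1774, 1647 and 1670 for day 6 against day 2, 3781 for RA against DMSO, 2742 for RA against HMBA and 1608 for DMSO against HMBA. Averaged dye pairs with treatment and day as terms gave 6799 for RA, 5508 for DMSO, 6587 for HMBA, 1820 for RA against DMSO, 861 for RA against HMBA and 117 for DMSO against HMBA. Scale normalization gave 52 for RA day 6 against day 2, and leaving out DMSO day 2 gave 134 for DMSO against HMBA.

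Leaving out 1 array gave 48 to 259 calls for RA day 6 against day 2, 18 to 39 for DMSO, 70 to 98 for HMBA, and 123 to 191 for DMSO against HMBA. Nanog reversed sign from day 2 to day 6 without RA day 2 replicate 1 (-0.16) or RA day 6 replicate 2 (-0.37), within a range of -0.37 to 0.47 over the fits without 1 array. In HMBA it reversed without day 2 replicate 2 (0.13) or day 6 replicate 1 (0.043), within -0.54 to 0.13, and with scale normalization (0.033), in each case without a call. The mean of a gene's probe sets lost the calls of primitive endoderm (Nanog RNAi and DMSO), epiblast (RA), p53 response and imprinted genes (DMSO) and cell cycle (RA against DMSO), at adjusted p of 0.060 to 0.074. With fry, primitive endoderm (0.17) and Nodal and BMP signalling (0.053) were lost in DMSO and glycolysis and hypoxia (0.12) in HMBA, each for day 6 against day 2. So were cell cycle (0.48, RA against DMSO), streak (0.70, RA against HMBA) and primitive endoderm (0.070, DMSO against HMBA). The neural list reversed with fry in RA (adjusted p = 0.0074) and in HMBA day 6 against day 2 (adjusted p = 0.022). Fry also called 10 list tests on the RNAi arrays and 16 on the ratio arrays, in the same direction, that the main test did not call. For RA over days 2 to 6 it called 16 of 18 lists and the main test 9.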

Other observations

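The day-by-day tests were chosen after the treatment means had been seen, as were the genes named here. On day 2 RA and DMSO differed in Pou5f1 (log ratio, base taken as 2, 2 arrays per day). With RA Pou5f1 was already lower on day 2 by 1.31 ± 0.20 (adjusted p = 0.0017) while Nanog was at -0.22 ± 0.28 (adjusted p = 0.88). Nanog was called lower with RA on day 4, by 1.01 ± 0.28 (adjusted p = 0.042), and was at -0.17 ± 0.28 on day 6 (adjusted p = 0.77). With DMSO Nanog was lower on day 2 by 1.83 ± 0.28 (adjusted p = 0.0043) while Pou5f1 was at 0.24 ± 0.20 (adjusted p = 1.00) and was called lower on day 6 only, by 1.44 ± 0.20 (adjusted p = 0.00054). On day 4 it was at -0.67 ± 0.20 (adjusted p = 0.068; 0.0056 with dye orientation as a term). With HMBA Nanog was lower on day 2 by 1.17 ± 0.28 (adjusted p = 0.031) and Pou5f1 was at -0.14 ± 0.20 (adjusted p = 0.89), and by day 4 Pou5f1 had reached -2.05. Tested directly on day 2, RA and DMSO differed in Pou5f1 by -1.55 ± 0.28 (adjusted p = 0.016). Nanog differed by 1.61 ± 0.40, which was not called (adjusted p = 0.098, and 6.9e-06 with dye orientation as a term). Between RA and HMBA on day 2 Pou5f1 differed by -1.17 ± 0.28, which was not called either (adjusted p = 0.12, and 0.0053 with dye orientation as a term). The change from day 2 to day 6 gave no called difference between inducers for either gene, with or without dye orientation as a term (adjusted p 0.24 or more in each pair).

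Krt18 and Igf2 did not rise on the ratio arrays where their partner genes did. Krt8 rose by 3.01 ± 0.09 with RA while Krt18, which pairs with it in simple epithelia, was at -0.24 ± 0.12 (adjusted p = 0.20; 0.017 with dye orientation as a term). Of the imprinted neighbours H19 changed by 4.50 ± 0.14 and Igf2 by -0.38 ± 0.13 (adjusted p = 0.045), whereas Igf2 rose by 6.32 ± 0.09 after Pou5f1 RNAi. Over all treatments and days the means of 2 arrays lay for Krt18 between -0.35 and 0.03 and for Igf2 between -0.64 and 0.17, also in HMBA, where Krt8 and H19 rose. Each of these values comes from 1 probe per gene, and the probes of Krt18 and Igf2 may not respond.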
